A study of Mus musculus with 4 samples.

How the data were processed

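Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map binding of Foxo1 in mouse regulatory T cells. Foxo1 is a forkhead transcription factor that is held out of the nucleus when PI3K and Akt signalling is active. The series comprised 4 libraries, 1 per group: a precipitation with a Foxo1 antibody from wild-type cells, a precipitation with streptavidin from cells of Foxo1tagBirA mice, and 1 input library for each. In the Foxo1tagBirA mice the endogenous Foxo1 protein is biotinylated by the bacterial ligase BirA, so that streptavidin captures it without an antibody. Libraries were made from sonicated nuclei, amplified by PCR for a number of cycles that varied between libraries, size-selected on a gel and sequenced on an Illumina Genome Analyzer, per the labels' protocols.

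Per the submitters' processing notes, CASAVA 1.4, Bowtie 0.12.7 and MACS 1.4 were used with the mouse build mm9; the notes give no roles or settings. CASAVA is Illumina's base-calling and demultiplexing software, Bowtie an aligner and MACS a peak caller. The deposited data analysed here were 3 lists of genomic intervals. The antibody and streptavidin lists give, for each peak called by the authors, its chromosome, start, end and a score, and their names state a false discovery rate of 0.01. No header defines the score. It was read as the peak caller's own value per peak, which MACS 1.4 derives from the negative log10 of a p-value, and was used mainly to rank and describe peaks within a list. A cutoff of 100 was also applied to both lists, although a given score need not mean the same in both, and a test of X copy number assumed that scores scale with copies. The third deposited list gives positions only. It is attached to the antibody input library but named for both methods, and its content was therefore compared with the other lists by coordinates before use. As 1465 of its intervals have an end at no end of a deposited peak, it may come from another set of peak calls, and its counts and densities describe the list as deposited. Whether peaks were called on 1 library or on pooled libraries, and which input served as control, is not given in the sources used here. No values of the input libraries themselves were analysed here.

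The lists hold no read counts, so the sequencing depth of each library is unknown and no counting floor was computed. With 1 library per group there is no replicate error. Every p-value below compares deposited lists of peaks and does not measure the spread between animals or libraries, and exact 95% binomial (Clopper-Pearson) intervals cover counting error over peaks only. Peaks within 1 region are not independent of each other. The authors' threshold decides how many peaks each list holds, and peaks just under it are missing, so a peak counted as unshared may still have had signal in the other library.

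Lists were read and compared with Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1. An antibody peak was counted as shared when it overlapped a streptavidin peak by at least 1 base, and the reverse for streptavidin peaks. The overlap expected by chance was taken from 10000 circular shifts of the antibody peaks within each chromosome, between the outermost peaks of the 3 lists, with a one-sided test; 1000 shifts were used for the streptavidin list, the distances and the alternatives. Scores and widths of shared and unshared peaks were compared within each list by a two-sided permutation test of the difference of medians with 100000 resamples. Peaks per chromosome were compared between the lists by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 21 chromosomes and a threshold of 0.05. Densities per Mb use the span between the outermost peaks as the chromosome's length. Coordinates are given in mm9, counted from 1.

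The overlap counts equalled those of bedtools 2.31.1 for 3 definitions of overlap. The shift test was tested on simulated data, with 16473 and 57748 intervals of the real widths placed at random. Intervals that overlapped an earlier one of their list were dropped, except in the antibody-sized lists with planted peaks, so the other lists were shorter. Each simulated pair had fewer shifts than the real lists. Of 40 pairs of unrelated lists, 1 passed the 0.05 threshold. The 500 planted shared peaks were recovered as a mean excess of 497 ± 11.3 peaks (SD over 10 simulated pairs). The intervals were placed uniformly, without the clustering and the shared regional density of the real lists. The error rate of the test on clustered lists was not checked.

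The tests, the alternatives and the peaks to be named were fixed before the data were examined, with these exceptions, which were added afterwards: the distances between peak centres, with their random placement and the tests of near but unshared peaks, the correlation of scores in shared regions, the test of the top against the bottom decile of scores, the ratio of X to autosome density with its alternatives, the comparisons of scores and score classes between X and the autosomes, the counts per 1 Mb window with their correlations, and 3 alternatives of the overlap. The predictions used to weigh explanations were all written after the data were seen. The rule named the 15 shared regions with the highest value of the smaller of their 2 within-list score percentiles, and the 5 highest-scoring peaks of each list that overlapped no peak of the other. Ties were resolved by the larger percentile and then by position, a choice made after the data were seen. The alternatives were stricter definitions of overlap, higher score thresholds, lists of equal length, other ways of placing peaks at random and the removal of the widest peaks. Comparisons that need the mm9 genome or its gene annotation (position relative to genes, 16 gene lists fixed beforehand, and sequence motifs) were not analysed here, because the gene table used for names is of build GRCm38 and coordinates of different builds were not mixed. The same holds for the 9 genes that were to be named in every list. Peaks are therefore named by position.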

Results

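Foxo1 binding was mapped in mouse regulatory T cells (nTreg in the labels) by 2 routes, an antibody against the endogenous protein in wild-type cells and streptavidin capture of biotinylated Foxo1 in cells of Foxo1tagBirA mice. The antibody list held 16473 peaks with a median width of 233 bases (quartiles 186 and 288), covering 4.20 Mb. The streptavidin list held 57748 peaks, 3.51 times as many, with a median width of 221 bases (quartiles 194 and 239), covering 12.9 Mb. The third list, of both methods, held 3431 intervals with a median width of 453 bases, covering 1.70 Mb. Each list stands for 1 library or 1 combination of libraries without replicates, and the read depth is unknown.

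Scores were read as the authors' peak caller's own values. They ranged from 86.0 to 3226 in the antibody list (median 167) and from 53.0 to 2748 in the streptavidin list (median 74.7). Many peaks took the same score. In the streptavidin list 2669 peaks, or 4.62%, had the score 53.1, and in the antibody list 323 peaks, or 1.96%, had the score 131.91. At the upper end 32 antibody peaks had exactly the score 3100 and 9 scored above it. The value 3100 may be a cap, in which case peaks at 3100 need not be weaker than those above it. The order of the strongest antibody peaks is therefore not resolved.

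The first comparison asked which peaks were called with both methods. Whether each peak is a site bound by Foxo1 was not tested. A total of 3600 of the 16473 antibody peaks, or 21.9% (95% exact interval 21.2 to 22.5), overlapped a streptavidin peak, and 12873 did not. In the other direction 3581 of the 57748 streptavidin peaks, or 6.20% (6.01 to 6.40), overlapped an antibody peak, and 54167 did not. Circular shifts of the antibody peaks gave 186 ± 14.2 overlaps (SD over 10000 shifts), so the observed number was 19.3 times the chance value (one-sided permutation p = 0.0001, the smallest the shifts can give). With the streptavidin list limited to its 16473 highest-scoring peaks, 13.1% of the antibody and 12.7% of those streptavidin peaks were shared. Among peaks of both lists with a score of at least 100, the shares were 11.5% of the antibody and 16.1% of the streptavidin peaks.

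Within shared regions the peak centres of both methods lay closer together than overlap alone requires. The shared peaks formed 3469 merged regions, of which 3246 contained 1 peak of each list. The centres of the strongest peak of each list in a region were a median of 56 bases apart (quartiles 25.5 and 109.5), and in 1592 regions, or 45.9%, they were within 50 bases. In the 3246 regions with 1 peak of each list the median was 53 bases, against 144 ± 2.42 for peaks of the same widths placed at random so that they overlap (SD over 10000 placements, one-sided permutation p = 0.0001, the smallest the placements can give). Across all 3469 merged regions the scores of the strongest peak of each list were correlated with a Spearman's rho of 0.37 (permutation p = 0.0001, two-sided, the smallest the permutations can give). That correlation is across regions, which are not independent replicates.

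Sharing was most frequent among the strongest peaks of each list. In the top decile of antibody scores 63.6% of the peaks (61.2 to 65.9) were shared, against 13.7% (12.03 to 15.4) in the bottom decile (Fisher's exact test, two-sided, adjusted p = 5.68e-202). The lowest 6 deciles of the antibody list had shares of 11.5% to 14.5%, with 13.1% (12.5 to 13.8) for these deciles as a whole, above the 1.13% given by circular shifts. In the streptavidin list the top decile was shared at 24.6% (23.5 to 25.7) and the bottom decile at 4.12% (3.62 to 4.67; Fisher's exact test, two-sided, adjusted p = 1.6e-235). The streptavidin share did not rise steadily, since it was lowest in deciles 4, 5 and 6, at 2.34% (1.96 to 2.76), 2.46% (2.08 to 2.89) and 3.10% (2.67 to 3.58), below the bottom decile. Of the top 1% of each list, 141 of 164 antibody peaks (86.0%, 79.7 to 90.9) and 509 of 577 streptavidin peaks (88.2%, 85.3 to 90.7) were shared. Of the 41 antibody peaks with a score of 3100 or more, 35 were shared and 6 were not.

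**Figure D1:**
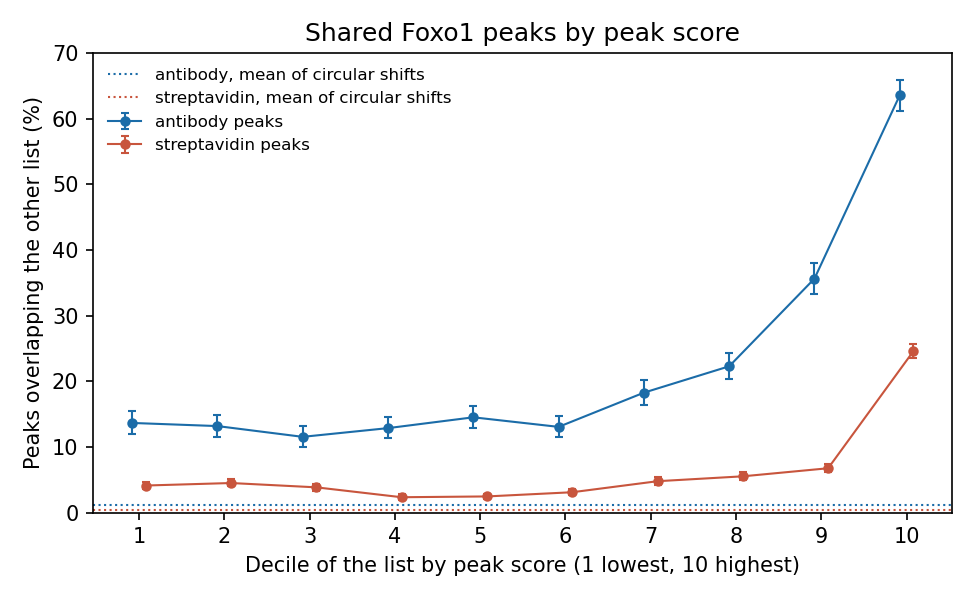
Percent of peaks that overlap the other list, by decile of the list ranked by peak score, for antibody peaks and streptavidin peaks; bars are exact 95% binomial intervals and dotted lines the means of circular shifts. The antibody share is 13.7% in decile 1 and 63.6% in decile 10, and the streptavidin share 4.12% and 24.6%.

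Shared peaks were also wider. In the antibody list the median score was 252 for shared and 158 for unshared peaks, and the median width 295 against 223 bases. In the streptavidin list the median score was 98.0 for shared and 74.0 for unshared peaks, and the median width 288 against 219 bases. All 4 differences had a permutation p of 1e-05 (two-sided, adjusted p = 1e-05), the smallest the resamples can give.

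The 15 shared regions that ranked highest in both lists lay on 11 chromosomes, were 295 to 1332 bases wide and were all part of the third list. The region ranked first was at chromosome 2, 170144660 to 170144954, with scores of 3144 in the antibody and 1195 in the streptavidin list and centres 10 bases apart. It was followed by a region at chromosome 7, 90803686 to 90804239, with scores of 3204 and 781. The next regions were at chromosome 1, 182125842 to 182126345 (3141 and 685), and at chromosome 7, 137690247 to 137690617 (3140 and 538). The other 11 regions had an antibody score of 3100, a value at which 20 shared regions were tied in rank. As 3100 may be a cap, these regions need not be weaker than the ones ranked above them. The highest streptavidin score of all, 2748, belonged to the region at chromosome 14, 8930449 to 8930848. The region at chromosome 4, 33334428 to 33335759, scored 2642 in the streptavidin list, and its centres were 325.5 bases apart, the largest distance among the 15.

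Further regions of this group lay at chromosome 13, 94269132 to 94269997, with a streptavidin score of 1702, and at chromosome 14, 65962510 to 65963060, with 1438. On chromosome 2 the interval 19579042 to 19579619 had a streptavidin score of 1425, and on chromosome 8 the interval 87502198 to 87502990 had 1378. A region at chromosome 13, 81025256 to 81025693, scored 1355, and one at chromosome 15, 79757964 to 79758559, scored 1205. The remaining 3 were at chromosome 3, 96361523 to 96361988 (1183), chromosome X, 39502079 to 39502518 (1086), and chromosome 6, 31166323 to 31166957 (1029).

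Strong peaks that overlapped no peak of the other list were also present. The highest-scoring antibody peak without a streptavidin overlap was at chromosome 8, 127421512 to 127421808, with a score of 3194 and the nearest streptavidin centre 2777 bases away. The following antibody peaks had a score of 3100, which may be a cap, so they need not be weaker. They lay at chromosome 2, 24774863 to 24775354, chromosome 5, 116081680 to 116082102, chromosome 8, 72758291 to 72758631, and chromosome 10, 80655099 to 80655688. Their nearest streptavidin centres were 10181.5, 12774, 22349 and 37256 bases away. The highest-scoring streptavidin peak without an antibody overlap was at chromosome 18, 82861677 to 82862052, with a score of 682, and an antibody peak was centred 383.5 bases from it. The next were at chromosome 8, 23303059 to 23303468 (score 391), chromosome 2, 29475064 to 29475359 (360), chromosome 3, 63733010 to 63733429 (343), and chromosome 19, 45122517 to 45122837 (332). Their nearest antibody centres were 26345.5, 168000, 35305 and 741.5 bases away, in that order.

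Antibody peaks lay near streptavidin peaks more often than shifted peaks did, beyond those that overlapped. Within 1 kb of the centre of 4939 antibody peaks, or 30.0%, there was a streptavidin centre, against 762 ± 32.1 after circular shifts (SD over 1000 shifts, 6.48-fold, one-sided permutation p = 0.000999, the smallest the shifts can give). Of the unshared antibody peaks, 1339, or 10.4%, had a streptavidin centre within 1 kb, against 3.53 ± 0.165% of the peaks left unshared after a shift (2.94-fold, one-sided permutation p = 0.000999). At 50 kb the difference from the shifts was 1.16-fold, with 15748 antibody peaks observed and 13552 ± 107 expected. These shifts ran over whole chromosomes and did not keep regional density. Local shifts were not made for these distances, so part of each excess may come from regions rich in peaks of both lists.

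**Figure D2:**
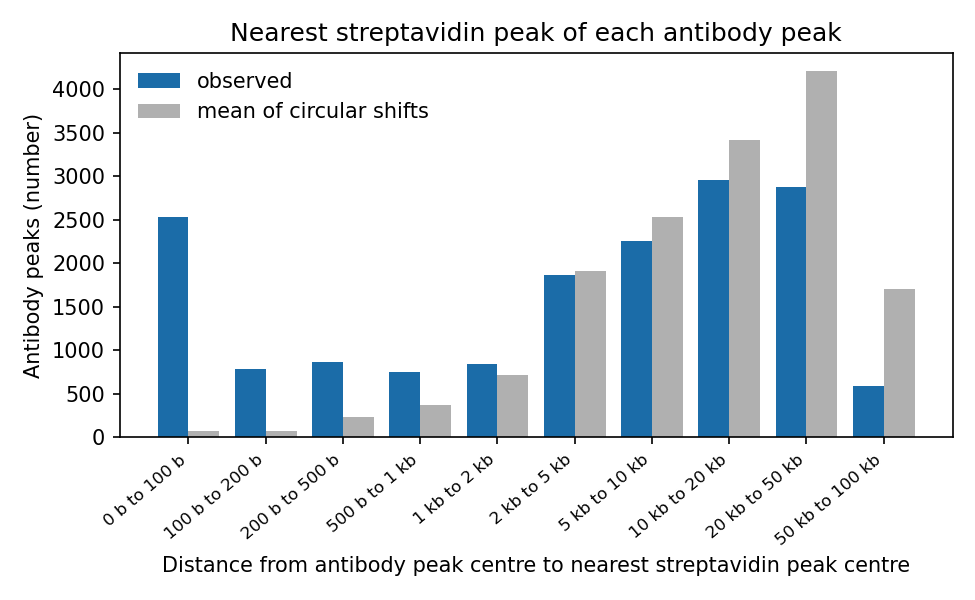
Number of antibody peaks by the distance from their centre to the nearest streptavidin peak centre, observed and as the mean of 1000 circular shifts; peaks farther than 100 kb from any streptavidin peak are not drawn. Observed peaks exceed the shifted ones up to 2 kb, with 2536 against 78.0 in the nearest class.

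The third list covered the regions called in both lists but could not be rebuilt from them. All 3431 intervals overlapped a peak of both the antibody and the streptavidin list, and all 3469 merged regions with peaks of both lists were met by it. Of its intervals 1956, or 57.0%, were identical to a merged region and 38 met 2 merged regions. A further 1437 met 1 merged region and reached beyond it, by a median of 112 bases. At least 1 end of 1465 intervals coincided with no end of a peak in the other lists. The intervals also met 95 antibody peaks and 44 streptavidin peaks that did not overlap a peak of the other list.

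The peaks were unevenly distributed over the chromosomes, with a smaller range between autosomes in the streptavidin than in the antibody list. The antibody list was densest on chromosome 11, with 10.4 peaks per Mb, and on chromosome 19, with 8.86 peaks per Mb, and sparsest among the autosomes on chromosome 3, with 5.03 peaks per Mb, a 2.06-fold range. Streptavidin peaks ranged from 21.8 per Mb on chromosome 3 to 28.1 per Mb on chromosome 11, a 1.29-fold range. The third list had 2.42 intervals per Mb on chromosome 11 and 2.21 on chromosome 19, against 0.97 on chromosomes 3 and 14. As shares of each list, 8 chromosomes were higher in the antibody list and 6 in the streptavidin list, and 7 did not pass the threshold (Fisher's exact test, two-sided, adjusted over 21 chromosomes). The test takes peaks as independent. A peak of the same list lay within 1 kb of 16.4% of antibody and 5.95% of streptavidin peaks, and neighbours were not joined here. These p-values may therefore be too small and the chromosomes past the threshold too many. Chromosome 11 held 7.47% of the antibody and 5.76% of the streptavidin peaks (odds ratio 1.32, Fisher's exact test, adjusted p = 7.65e-14). Chromosomes 5, 7, 10, 15, 17, 19 and Y were also higher in the antibody list. Chromosome 18 held 2.82% and 3.65% (odds ratio 0.765, Fisher's exact test, adjusted p = 7.22e-07), and chromosomes 1, 3, 13, 14 and 16 were likewise lower in the antibody list. With peaks of a score of at least 100 alone, 8 of the 14 differences remained past the threshold in the same direction, and those of chromosomes 10, 14, 16, 17, 19 and Y did not. Fewer peaks were tested at that score. The odds ratio was 1.10 on chromosome 10, 1.13 on chromosome 17 and 1.19 on chromosome 19, against 1.17, 1.17 and 1.13 in all peaks. On chromosomes 14 and 16 it was 0.931 and 0.942, against 0.880 and 0.873. In the higher-scoring 50% of each list 11 remained, and those of chromosomes 15, 16 and Y did not. There the odds ratio was 1.09 on chromosome 15, against 1.11 in all peaks, and 0.858 on chromosome 16, against 0.873.

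Chromosome X carried few peaks in each list. It had 182 antibody peaks, 1.13 per Mb, against 6.77 per Mb on the autosomes, a ratio of 0.167 (95% exact interval 0.143 to 0.193). It had 647 streptavidin peaks, 4.01 per Mb against 23.7 per Mb, a ratio of 0.169 (0.156 to 0.183). In the third list the ratio was 0.194 (0.141 to 0.261), from 44 intervals. The share of peaks on X was 1.10% in the antibody and 1.12% in the streptavidin list (odds ratio 0.986, Fisher's exact test, adjusted p = 0.938). Of the antibody peaks on X 46, or 25.3% (19.1 to 32.2), were shared, a share whose interval includes the 21.9% of the whole list. Chromosome Y had 9 antibody and 5 streptavidin peaks (Fisher's exact test, adjusted p = 0.00201) and no interval of the third list. Its difference did not pass the threshold in the higher-scoring 50% of each list, with 2 against 0 peaks (Fisher's exact test, adjusted p = 0.0793), or at scores of at least 100, with 7 against 0 (Fisher's exact test, adjusted p = 0.0976).

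**Figure D3:**
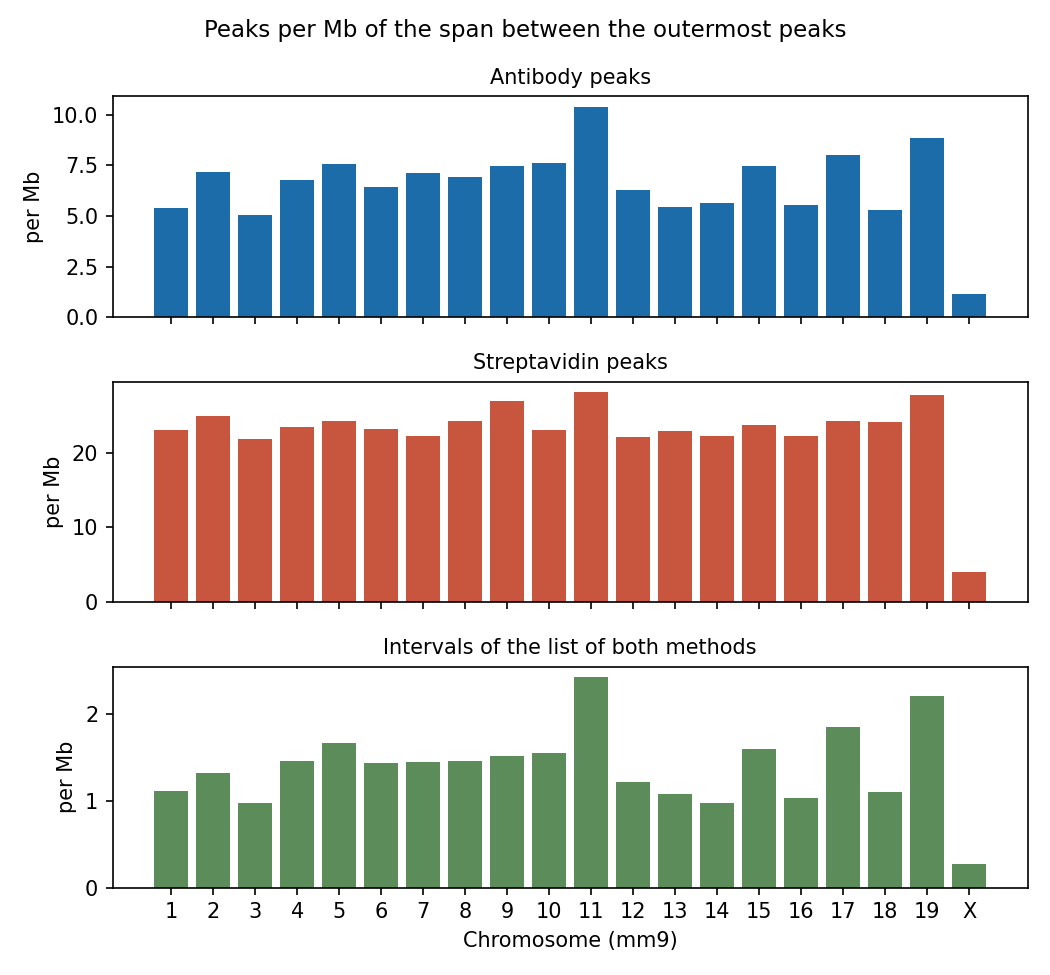
Peaks per Mb on each chromosome for the antibody list, the streptavidin list and the list of both methods, with the span between the outermost peaks as the length; chromosome Y is left out because its peaks span only 2.28 Mb. Chromosome 11 is highest in each list (10.4, 28.1 and 2.42 per Mb) and chromosome X lowest (1.13, 4.01 and 0.273 per Mb).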

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

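All 12 other ways of defining or placing peaks left the overlap above chance, at 6.51 to 53.2 times the shifted value (each one-sided permutation p = 0.000999); 3 of them (no X and Y, centres within 1 kb, neighbours within 1 kb joined) were chosen after seeing the data. The share of antibody peaks counted as shared moved from 21.9% to 19.7% with an overlap of 50% of the shorter peak, 15.8% with 50% of each peak, 20.2% with centres within 200 bases, 11.5% with scores of at least 100, 23.6% in the higher-scoring 50% of each list, 13.1% with lists of equal length, 18.7% without the widest 1% of peaks and 30.0% with centres within 1 kb. The streptavidin share moved in the same order from 6.20% to 5.63%, 4.50%, 5.74%, 16.1%, 6.75%, 12.7%, 5.32% and 8.05%, and was 5.99% with neighbouring peaks joined. A score of 100 removes most streptavidin but few antibody peaks, which by construction lowers the antibody share; the streptavidin peaks it keeps are the higher-scoring ones, which were shared more often (24.6% in the top against 4.12% in the bottom decile). The score and width differences kept their direction and stayed past the threshold. Chromosomes with a higher antibody share fell from 8 to 4 with scores of at least 100, where fewer peaks were tested, and chromosome Y was not among them. The ratio of X to autosome density, also chosen after seeing the data, was 0.211 for antibody and 0.207 for streptavidin peaks in the higher-scoring 50%. At scores of at least 100 it was 0.169 for antibody and 0.204 for streptavidin peaks. The cause of the differences between settings was not tested. No replicate could be left out, since each group has 1 library. Alternatives on genes and motifs were not run without the mm9 genome. Read depth is unknown, so whether unshared peaks fell just under the threshold in the other library cannot be measured here.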

Other observations

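Except for the local shifts of 10 to 100 kb and the shares by decile of score, which were planned, the tests in this part were chosen after the data were seen. In fixed windows of 1 Mb, intervals of the third list clustered most on chromosome 10, 79000001 to 80000000, with 15 intervals, 48 antibody peaks and 47 streptavidin peaks. The median autosomal window had 1, 5 and 24. The next windows were chromosome 11, 106000001 to 107000000 (12 intervals, 28 antibody and 31 streptavidin peaks), chromosome 17, 29000001 to 30000000 (12, 27 and 44), chromosome 19, 5000001 to 6000000 (11, 43 and 39), and chromosome 17, 84000001 to 85000000 (11, 27 and 35). Of 2382 autosomal windows, 302 had no antibody peak and 35 no streptavidin peak.

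The number of peaks per window was correlated between the methods across the 2382 autosomal windows (Spearman's rho 0.73, highest value after circular shifts 0.096, permutation p = 0.0001, the smallest the shifts can give). Over peaks that overlapped no peak of the other list, rho was 0.65 (permutation p = 0.0001). Windows are not independent replicates. Antibody peaks had another antibody peak within 1 kb in 16.4% of cases, and streptavidin peaks another streptavidin peak in 5.95%. No test was made of that difference. Median scores on chromosome X were above those on the autosomes, 197 against 167 in the antibody list (two-sided permutation p = 0.0004) and 78.3 against 74.7 in the streptavidin list (two-sided permutation p = 0.0001).

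Most antibody peaks overlapped no streptavidin peak, although overlap was far above chance. Broad regions rich in peaks are argued against as the reason for the overlap, since moving each antibody peak by 10 to 100 kb left the observed number 14.3 times the expected one. Weak peaks missed near the calling threshold are a candidate explanation for part of the unshared peaks. In the antibody list 63.6% of the top decile of scores were shared, against 13.7% of the bottom decile. The share did not rise from the bottom, however, and was 11.5% to 14.5% over the lowest 6 antibody deciles. In the streptavidin list it was 4.12% in the bottom decile and 2.34% in decile 4. The comparison of the end deciles therefore does not settle this explanation. The unshared antibody peaks within 1 kb of a streptavidin centre may in part come from stretches split into several antibody peaks of which 1 is shared. Of these 1339 peaks, 520 had a shared antibody peak within 1 kb. The streptavidin peak that overlaps the shared neighbour is then mostly close as well. The count therefore cannot tell a split stretch from separate sites that lie near each other. That kind of split is argued against as the whole cause: of the 12340 unshared antibody peaks without such a neighbour 819, or 6.64%, had a streptavidin centre within 1 kb, 1.98 times the 3.36 ± 0.158% after shifts (one-sided permutation p = 0.000999). Those shifts ran over whole chromosomes, so regions rich in peaks of both lists may account for part of this excess. A stretch called as adjacent peaks of each list that do not overlap stays open and was not tested. The method and the mouse line change together in this design, so a difference between wild-type and Foxo1tagBirA cells stays open and untested, as do accessible chromatin recovered by either method and unspecific signal.

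The density of peaks on chromosome X was 0.167 and 0.169 times that on the autosomes in the antibody and streptavidin lists. An effect in the antibody library alone is argued against by the value of the streptavidin list. A loss confined to weak X peaks is argued against by the ratio of 0.221 (0.141 to 0.329) in the top decile of antibody scores. That decile uses 1 score cutoff for all chromosomes. A cause that lowered every X score would also lower this ratio, so the ratio cannot decide on such a cause. The called X peaks did not score lower, with medians of 197 against 167 on the autosomes in the antibody list. In the streptavidin list the medians were 78.3 and 74.7. These medians leave out peaks under the threshold, and the medians expected under lowered X scores were not computed. A single X copy that halved every score could leave X with the density of autosomal peaks at or above 2 times the lowest score; the observed X density was 0.351 times that in the antibody and 1.11 times that in the streptavidin list. This stays open because the scaling of scores with copy number was assumed and the sex of the mice is not in the labels. Both lists held peaks on chromosome Y (9 antibody and 5 streptavidin), but whether they reflect male cells was not tested. The number of uniquely mappable bases and of genes on X was not tested, and no biological explanation was tested.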
